A study of Mus musculus with 24 samples.

How the data were processed

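RNA from mouse embryonic fibroblasts was measured on 24 oligonucleotide arrays. Per the labels, the cells were primary fibroblasts at passage 3, either wild type or CHOP-/-, and total RNA was used. CHOP is the transcription factor encoded by Ddit3. Per the labels, cells were left untreated or were given tunicamycin at 2 µg/ml for 4 h or 8 h. Tunicamycin blocks N-linked glycosylation, so that unfolded proteins gather in the endoplasmic reticulum (ER). Each of the 6 groups held 4 arrays with the letters A to D. Nothing in the labels says that the 4 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples.

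The deposited values were probe set signals (unit: intensity). From the values, they were linear, were given to 1 decimal and covered 12488 probe sets, including 66 control probe sets. The mean of each array after removal of 2% of probe sets at each end lay between 250.1 and 250.2, so the arrays had been scaled to a common trimmed mean before deposit. The software and the scaling are not given in the sources used here. The median signal lay between 48.2 and 72.6. On control probe sets the ratio of 3' to 5' signal was 0.75 to 0.85 for Gapdh and 0.95 to 1.24 for actin. For arrays the number of arrays, 4 per group, limits the precision.

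Probe sets were joined to genes through the gene table supplied for the array, which listed 11251 of them. Of these, 10855 had 1 gene and 396 had several. The other 1237 had none. After removal of controls, 10833 probe sets with 1 gene remained, and 10817 of them had an identifier found in the RefSeq gene table for GRCm38.p6, which was used only for names and gene neighbourhood. They stood for 8251 genes, 2073 of them with more than 1 probe set, and the probe set with the highest mean signal stood for its gene. Probe sets with several gene names or none were tested apart. Of 188 genes with more than 1 tested probe set and at least 1 of them called at 8 h in wild type cells, 22 had probe sets of opposite sign and 1 had calls in opposite directions.

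A pseudocount of 5.7, the 20th percentile of all signals, was added before taking log2. Fold changes are therefore on the log2(signal + pseudocount) scale and understate the change of genes with low signals. The array medians of wild type 4 h A and C lay 0.266 above and 0.273 below the mean of all medians. Both exceeded a limit of 0.2 fixed earlier, and the log2 values were quantile normalized. A gene was tested if its mean log2 value exceeded 5.064, a signal of 27.7 at the 40th percentile. That left 5692 genes. Besides Car6, every array of 1 group lay under a signal of 27.7 in 7 of 221 named values, for Rabepk, Amacr, Rab3d and Npy1r, so the log2 changes of these genes are not exact sizes. A linear model over 6 group means of all 24 arrays was fitted with limma 3.58.1 in R 4.3.3, with moderated statistics and an intensity trend (residual degrees of freedom 18, prior 5.2). A gene was called when its two-sided p, adjusted by the Benjamini-Hochberg method within a contrast, was under 0.05. There were 11 contrasts. They compared 4 h and 8 h with untreated cells and 8 h with 4 h in each genotype, CHOP-/- with wild type cells at each time, and the responses of the genotypes at 4 h and at 8 h. The last are the change in CHOP-/- cells less the change in wild type cells. The median standard error (SE) of a log2 change was 0.189, and 0.268 for a response difference. Ddit3 was also tested by an exact two-sided permutation test of group means. With 4 arrays against 4, complete separation of a gene's arrays has an exact p of 0.0286. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

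Genes were named by a rule. Ddit3, Hspa5, Hsp90b1, Dnajb9, Herpud1, Xbp1, Atf3, Atf4, Trib3, Asns, Ppp1r15a, Ero1a and Car6 were always named. In each wild type response the 10 largest rises and 10 largest falls qualified among called genes whose arrays did not overlap between the groups. The number was 5 in each CHOP-/- response, 8 in each genotype difference and each response difference (for the latter without the condition on overlap) and 4 for 8 h against 4 h. From each list, up to 4 members with the smallest adjusted p and any called member against the direction of the list could be named.

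The 31 gene lists covered ER chaperones and folding enzymes, ER-associated degradation, ER translocation and vesicle transport, N-glycosylation, PERK-ATF4 genes, aminoacyl-tRNA synthetases, amino acid transporters, reported CHOP-dependent genes, BCL2 family and cell death, cell cycle and DNA replication, extracellular matrix, cholesterol, NRF2, p53, immediate-early, interferon-stimulated, chemokine and cytokine, glycolysis and hypoxia, proteasome, ribosomal protein, respiratory chain and translation initiation genes, genes near Ddit3, and markers of skeletal and cardiac muscle, smooth muscle, leukocytes, epithelium, endothelium, neural cells, cartilage and bone, and adipocytes. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with a correlation estimated from the data. Of 341 tests, 105 were called and 26 of these also with the estimated correlation. The reported CHOP-dependent genes were listed from memory of earlier work.

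The groups, tests, lists, naming rule and alternative settings were fixed before the data were examined, except for 2 added settings, 3 added lists and the tests named in the closing section. The alternatives were values as deposited, centring on the median, other pseudocounts and filters, every probe set, no trend, a robust fit, array weights, a fit to the compared groups only, a block for the letters and leaving out each array in turn. The added settings left out the untreated and 4 h CHOP-/- arrays C, or the 6 wild type arrays A and B. Both were chosen after seeing the data. No scaling moved the median change of all genes by over 0.1.

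Whether letters pair the arrays was checked by correlating residuals of arrays with the same letter. In all 4 letters the correlation exceeded 0.1 between untreated and 4 h wild type arrays (0.32 to 0.55), untreated and 8 h wild type arrays (0.4 to 0.62), 4 h and 8 h wild type arrays (0.25 to 0.61), untreated wild type and 8 h CHOP-/- arrays (0.21 to 0.47), and 8 h arrays of both genotypes (0.29 to 0.55), but not between the other groups. What the letters share is not given in the sources used here.

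The method was tested on simulated data with the same number of arrays. For 8 h against untreated in wild type cells, 24% of 0.5 log2 changes, 79.2% of 1 log2 changes, 93.6% of 1.5 log2 changes and 93.9% of 2 log2 changes were called, and 4.8% of the calls were false. For CHOP-/- against wild type at 8 h the shares were 32%, 74.5%, 89.6% and 98%, with 5.3% false. For the response difference at 8 h they were 6%, 48.9%, 91.5% and 91.8%, with 5% false. A shift of 0.3 planted in the 29 proteasome genes was called with an adjusted p of 3e-16, and none of the 30 other lists was. The simulated noise was independent between genes and between arrays, unlike the data. The simulation therefore cannot show how often genes or lists are called falsely where genes or arrays correlate.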

Results

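Gene expression was measured in primary mouse embryonic fibroblasts that met ER stress with or without CHOP. CHOP, encoded by Ddit3, is a transcription factor of the PERK arm of the unfolded protein response. Wild type and CHOP-/- cells were each compared untreated, after 4 h and after 8 h of tunicamycin at 2 µg/ml, with 4 arrays per group and 24 arrays in total. The first principal component held 23.3% of the variance and the second 15%. The questions were which genes tunicamycin changed, which differed between the genotypes, and which responded to tunicamycin only or more strongly with CHOP. The labels give no time for the untreated cells and name no group with solvent alone. Changes after tunicamycin therefore cannot be told apart from changes with time or handling.

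Ddit3 itself was measured first. Its probe set gave a signal of 299.6 ± 97.4 (SD, n = 4) in untreated wild type cells, 3652 ± 722 at 4 h and 4383 ± 524 at 8 h. In CHOP-/- cells the signal was 14.68 ± 12 untreated, 31.58 ± 11 at 4 h and 20.5 ± 14.4 at 8 h. Every CHOP-/- array lay below every wild type array. The wild type arrays ranged from 215.5 to 437 untreated, from 2773.9 to 4396.6 at 4 h and from 3857 to 4883 at 8 h. The CHOP-/- arrays ranged from 6.9 to 32.3, from 15.6 to 40.4 and from 7.1 to 39 at the same times. Of the 4 CHOP-/- arrays, 3 untreated, 1 at 4 h and 3 at 8 h lay under the filter's signal of 27.7. With these arrays set to that signal, Ddit3 was at least 10.4-fold lower in CHOP-/- cells untreated, 106-fold at 4 h and 143-fold at 8 h. The fitted log2 differences between the genotypes, not exact sizes, were −4.05, −6.73 and −7.48 (SE 0.35 each), and the exact two-sided permutation p was 0.0286 at each time, the smallest that 4 arrays against 4 can give. At 8 h residuals paired the arrays of the genotypes by letter, so the permutation p there is not exact. Which part of the transcript the probe set reads is not given in the sources used here.

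In wild type cells, 4 h of tunicamycin raised genes of both the folding and the translational arms of the stress response. Herpud1, which serves ER-associated degradation, rose by 3.03 log2 (SE 0.107, adjusted p = 8.94e-16), from a signal of 550.7 ± 88.7 to 4486 ± 536 (SD, n = 4). Ddit3 rose by 3.60 log2, and Trib3, a pseudokinase gene downstream of ATF4 and CHOP, rose by 1.94 log2. Ppp1r15a, which encodes the GADD34 subunit of the eIF2α phosphatase, rose by 1.74 log2, and Atf4 rose by 0.91 log2. Rabepk (fitted 3.05, at least 4.86-fold), Piga (2.55), Gadd45a (2.34), Snhg5 (2.22), P2ry2 (2.13), Creld2 (1.92) and Ero1b (1.77) completed the 10 largest rises whose arrays did not overlap between the groups. Piga encodes an enzyme of glycosylphosphatidylinositol anchor synthesis. The falls were smaller, led by Adm (−1.71), Ptger4 (−1.69), Nr4a1 (−1.53), St6gal1 (−1.29) and Gas1 (−1.25). They were followed by Nr2f1 (−1.16), Idi1 (−0.97), Nrep (−0.96), Elovl6 (−0.96) and Hmgcs1 (−0.95), whose call ended in 11 of 21 other settings.

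Among the other always named genes, Dnajb9 rose by 1.60 log2, Ero1a by 0.61, Hspa5 by 0.56 and Xbp1 by 0.49 after 4 h in wild type cells. In a fit of every probe set without the filter, the other Dnajb9 probe set rose by 2.31 (adjusted p = 0.00482). In that fit the other Ero1a probe set was not called (0.58, adjusted p = 0.5). The Xbp1 call ended in 13 of 21 other settings. Hspa5, which encodes the chaperone BiP, went from a signal of 4037 ± 489 to 5443 ± 706 (SD, n = 4). Hsp90b1 (0.57, adjusted p = 0.161), Atf3 (0.42, adjusted p = 0.903) and Asns (0.25, adjusted p = 0.233) were not called. Car6, a carbonic anhydrase gene reported to depend on CHOP, lay below the filter, with a signal of 12.18 ± 10 untreated and 25.12 ± 3.44 at 4 h.

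**Figure D1:**
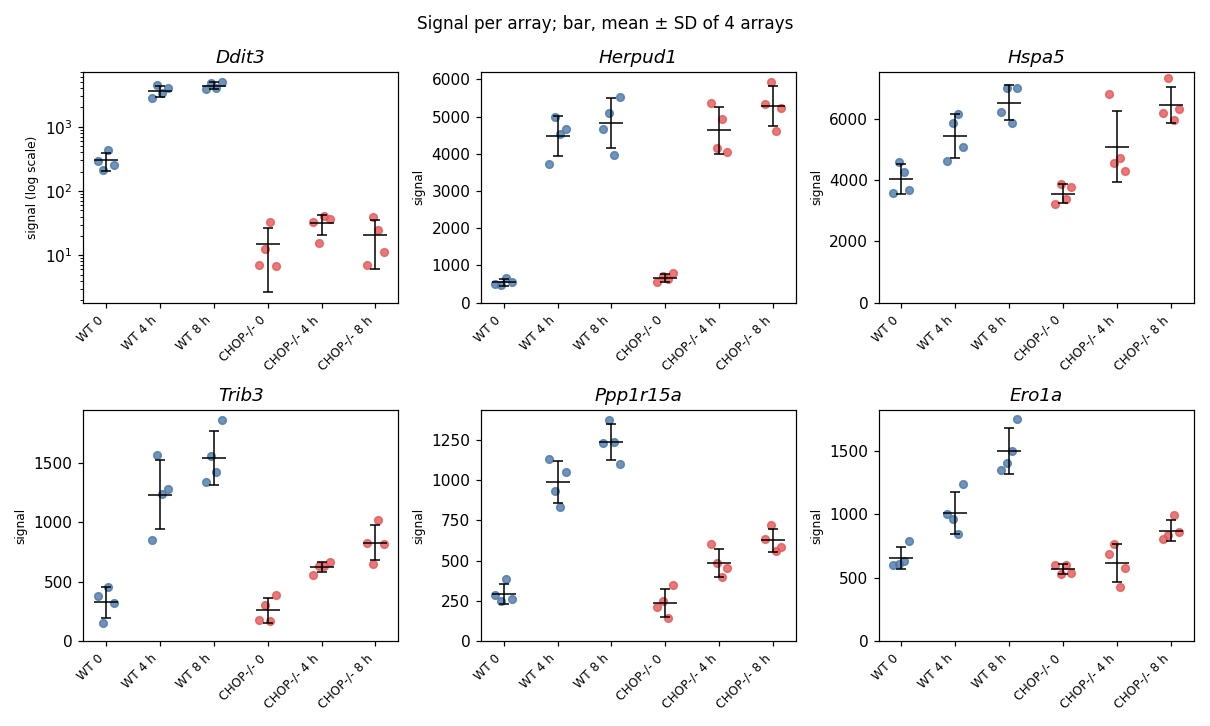
Signal (intensity) of Ddit3, Herpud1, Hspa5, Trib3, Ppp1r15a and Ero1a in each array of the 6 groups, on a log axis for Ddit3 and linear axes for the others; points are arrays and bars give the mean and SD of 4 arrays. On the probe sets shown, Ppp1r15a and Ero1a were called lower in CHOP-/- cells at 4 h and 8 h, and Trib3 was not. The other Ero1a probe set was called lower at 8 h but not at 4 h.

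In all, limma called 121 of 5692 genes at 4 h in wild type cells, 102 higher and 19 lower, of which 47 changed at least 2-fold. At an unadjusted p under 0.05 there were 633 genes, and the arrays of 394 genes did not overlap between the groups. For each single gene that has an exact p of 0.0286 by chance, so part of such a count arises by chance. The count fell to 62 without untreated array A, 79 without untreated array D, 77 without 4 h array A and 77 without 4 h array D. It was 80 with each array centred on its median, 70 with only the compared groups, 190 with array weights and 21 without arrays A and B.

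As lists, the PERK-ATF4 genes, which restore amino acid supply and translation, rose at 4 h in wild type cells. Of 22 measured, 7 rose and 10 did so adjusted over the list alone, with Cebpg (0.67) beside Atf4, Ppp1r15a and Trib3 (median 0.32 log2, camera adjusted p = 2.93e-12). Among ER chaperones and folding enzymes 7 of 22 rose, and 9 adjusted over the list alone, with Creld2, Dnajb9 and Pdia4 (1.25) first (median 0.21, adjusted p = 1.33e-08). In ER-associated degradation 4 of 16 rose, and 4 adjusted over the list alone, including Sel1l (0.90), Xbp1 and Derl1 (0.54), with an adjusted p of 2.43e-07. Of the reported CHOP-dependent genes 3 of 7 rose, and 4 adjusted over the list alone (median 0.52, adjusted p = 3.87e-06). These 4 lists were also called with an estimated correlation. The CHOP-dependent list is not independent evidence, since Ppp1r15a, Trib3, Chac1, Atf5 and Nupr1 also stand in the PERK-ATF4 list.

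Other lists were called at 4 h on few members. In the cholesterol list 2 of 17 genes fell, Idi1 and Hmgcs1, and 3 did so adjusted over the list alone (median −0.43, adjusted p = 1.16e-05, and adjusted p = 0.303 with an estimated correlation). Among immediate-early genes Nr4a1 and Btg2 (−0.91) fell while Myc rose by 0.98, a call that ended in 15 of 21 other settings, and 8 fell adjusted over the list alone (median −0.32, or −0.56 without 4 h array C, adjusted p = 0.000436, and adjusted p = 0.496 with an estimated correlation). The aminoacyl-tRNA synthetase genes, targets of ATF4, had a median of 0.20 with 1 of 20 called, Wars at 0.52 (adjusted p = 0.00143, and adjusted p = 0.0945 with an estimated correlation). Chemokine and cytokine genes had a median of 0.38 with 1 of 20 called (adjusted p = 0.007, and adjusted p = 0.272 with an estimated correlation), which ended without untreated array C (adjusted p = 0.0584) and had a median of 0.20 without untreated array D. Respiratory chain genes (median −0.14, adjusted p = 8.93e-05) and matrix genes (median −0.09, adjusted p = 0.0458) had no called member and were not called with an estimated correlation (adjusted p = 0.581 for both). The respiratory chain call ended without 4 h array A (median −0.07, adjusted p = 0.0774), and the matrix call without untreated array A, untreated array D or 4 h array C (adjusted p up to 0.304, with a median of −0.05 without 4 h array C).

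By 8 h in wild type cells Rabepk had the largest fitted rise, 4.73 log2 (SE 0.281, adjusted p = 3.21e-11), from a signal of 10.7 ± 3.63 to 437.2 ± 77 (SD, n = 4). Its untreated arrays all lay under the signal of the filter, so that the rise is at least 15.8-fold. Its gene is the neighbour of Hspa5 in the GRCm38.p6 annotation. Ero1b, an ER oxidase gene, rose by 3.76 log2 and Creld2, a folding factor gene, by 3.42 log2. Creld2 went from a signal of 337 ± 45.8 to 3717 ± 560 (SD, n = 4). Ddit3 (3.87), Herpud1 (3.09), Piga (2.99), Gadd45a (2.46), Snhg5 (2.42), Trib3 (2.28) and Dnajc3 (2.24) completed the 10 largest rises. Dnajb9 rose by 2.16 log2, Ppp1r15a by 2.02, Ero1a by 1.16, Hsp90b1 by 1.10, Atf4 by 0.88, Hspa5 by 0.74 and Asns by 0.46. In a fit of every probe set without the filter, the other Dnajb9 probe set rose by 3.84 log2 (adjusted p = 1.68e-06). That lies between the rises of Ddit3 and Ero1b. The other Ero1a probe set rose by 1.31 (adjusted p = 0.0011). Xbp1 (0.32, adjusted p = 0.103) and Atf3 (−0.05, adjusted p = 0.967) were not called.

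The largest fall at 8 h in wild type cells was that of Nr4a1, an immediate-early nuclear receptor gene, which fell by 4.73 log2 (SE 0.377, adjusted p = 5.1e-09), from a signal of 2505 ± 373 to 88.92 ± 34 (SD, n = 4). Idi1, which makes isoprenoid precursors, fell by 3.35 log2, from 956.6 ± 104 to 88.78 ± 28 (SD, n = 4). The prostaglandin receptor gene Ptger4 (−3.46), Fos (−3.30), the hyaluronan synthase gene Has2 (−2.85), Errfi1 (−2.72), Id1 (−2.63), Nrep (−2.57), F3 (−2.53) and Egr2 (−2.37) were the other large falls. Car6 without the filter was called (adjusted p = 3.35e-07) and rose at least 4.14-fold over the filter's signal of 27.7, to 114.8 ± 26 (SD, n = 4).

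Of 5692 genes 944 were called at 8 h in wild type cells, 549 higher and 395 lower, and 248 changed at least 2-fold. The count at an unadjusted p under 0.05 was 1581, and the arrays of 1174 genes did not overlap (exact p 0.0286 each by chance). Called genes were higher in 58.2% of cases, or in 68.6% with each array centred on its median. With array weights 1469 genes were called, and 296 without arrays A and B.

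At 8 h in wild type cells 15 of 22 ER chaperone genes rose, and 17 adjusted over the list alone (median 0.69, adjusted p = 3.58e-13, and 0.00564 with an estimated correlation). Pdia4 rose by 2.23 log2 and Manf by 1.46. In ER-associated degradation 11 of 16 rose, and 14 adjusted over the list alone (median 0.80, adjusted p = 1.54e-11), among them Sel1l (1.96), Derl1 (1.06) and Edem2 (0.93). In ER translocation and vesicle transport 14 of 43 rose, and 15 adjusted over the list alone, among them Sec23b (1.30), Stx5a, Lman2 (0.93) and Srp68 (0.74). That list had an adjusted p of 3.48e-06 and an adjusted p = 0.174 with an estimated correlation. In N-glycosylation, the process that tunicamycin blocks, 7 of 21 genes rose, and 8 adjusted over the list alone, with Alg2 (1.03), Gnpnat1 (0.98), Ddost (0.57) and Rpn1 (0.50) named (median 0.31, adjusted p = 0.000359). Except for transport, these lists were also called with an estimated correlation.

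Among PERK-ATF4 genes 13 of 22 rose at 8 h in wild type cells, and 14 adjusted over the list alone, with Stc2 at 1.59 log2 (median 0.50, adjusted p = 4.13e-10). Among aminoacyl-tRNA synthetases 13 of 20 rose, and 17 adjusted over the list alone (median 0.56, adjusted p = 1.54e-07). Wars (1.47), Lars (0.82) and Rars (0.65) rose, and Mars1, whose gene lies beside Ddit3 in GRCm38.p6, fell by 0.78 log2. Both lists and the reported CHOP-dependent genes, with 4 of 7 risen, and 4 adjusted over the list alone (median 0.95, adjusted p = 0.000427), were also called with an estimated correlation. Nupr1 (0.95) was the fourth of these besides Ppp1r15a, Trib3 and Ero1a. Of the amino acid transporter genes 5 of 11 rose, and 5 adjusted over the list alone, among them Slc7a5 (1.22), Slc6a9 (1.08), Slc3a2 and Slc7a3 (0.83). That list had an adjusted p of 0.0401 and an adjusted p = 0.103 with an estimated correlation, and its call ended without untreated array B or 8 h array C (adjusted p up to 0.0587).

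**Figure D2:**
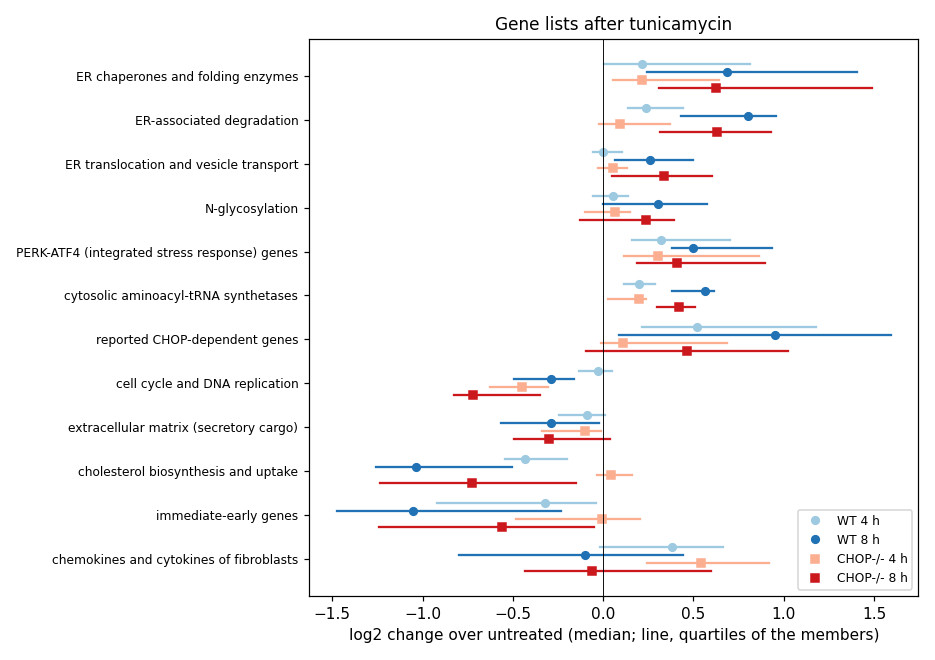
Median log2 change over untreated cells (horizontal axis; lines, quartiles of the members) of 12 gene lists in wild type (circles) and CHOP-/- cells (squares) after 4 h and 8 h of tunicamycin. The ER and PERK-ATF4 lists moved up and the cholesterol and immediate-early lists down at 8 h in both genotypes.

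Lists that went down at 8 h in wild type cells lost their calls with an estimated correlation. In the cholesterol list 10 of 17 genes fell, and 14 adjusted over the list alone, among them Hmgcs1 (−1.72), Msmo1 (−1.61) and Sqle (−1.26), while Mvd rose by 0.89 (median −1.04, adjusted p = 1.36e-08, and adjusted p = 0.119 with an estimated correlation). Of the immediate-early genes 13 of 22 fell, and 13 adjusted over the list alone, among them Junb (−1.60), Fosb (−1.48) and Jun (−1.36), while Myc rose by 0.83 (median −1.05, adjusted p = 1.23e-08, and adjusted p = 0.122 with an estimated correlation). Matrix genes, cargo of the secretory pathway, fell in 10 of 45 cases, and 11 adjusted over the list alone, led by Nid1, Timp3 (−1.31), Mfap2 (−1.21) and Ccn1 (−0.83), with an adjusted p of 2.86e-05 and an adjusted p = 0.123 with an estimated correlation. Of the cell cycle genes 6 of 42 fell, and 6 adjusted over the list alone, among them Birc5 (−0.84), Mcm3 (−0.65), Rfc3 (−0.58) and Pcna (−0.57), while Cdc45 (0.84) and Cdc6 (0.82) rose (median −0.29, adjusted p = 0.00122, and adjusted p = 0.523 with an estimated correlation). Respiratory chain genes fell in 5 of 61 cases, and 4 adjusted over the list alone, with Uqcrh (−0.78) and Cox7a2 (−0.48), at an adjusted p of 0.00122 and an adjusted p = 0.523 with an estimated correlation. Glycolysis and hypoxia genes fell in 5 of 18 cases, and 6 adjusted over the list alone, with Adm (−1.69), Pdk1 (−0.97), Bnip3 (−0.85) and Pfkp (−0.55), at an adjusted p of 0.039 and an adjusted p = 0.45 with an estimated correlation. The last call ended without untreated array A or B or 8 h array C or D (adjusted p up to 0.173).

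Cell death genes did not move as a group at 8 h in wild type cells. In the BCL2 list Birc2 and Bid (0.82) rose, and 4 of 22 genes fell, or 5 adjusted over the list alone, with Casp6 (−1.02) and Apaf1 (−0.58) (adjusted p = 0.509). Among p53 targets Gadd45a rose and Btg2 (−1.24) and Ccng1 (−0.46) fell, with 4 of 14 lower adjusted over the list alone, a median of −0.05, a mean of 0.04 and an adjusted p of 0.68. In the NRF2 list, the antioxidant response, Hmox1 (0.91), Sqstm1 (0.86) and Txnrd1 (0.59) rose while Gsr (−0.75) and Gstm1 (−0.62) fell (adjusted p = 0.867). Among chemokine and cytokine genes Nfkb2 (0.68), Relb (0.67), Vcam1 (0.60) and Csf1 (0.54) rose while 4 of 20 fell, and 5 adjusted over the list alone, with Ptgs2 (−1.26) and Nfkbia (−1.18) (adjusted p = 0.489). Interferon-stimulated genes fell in 2 of 15 cases, Ifi47 (−0.96) and Ifitm3 (−0.38), and in 3 adjusted over the list alone (adjusted p = 0.425). The Ifitm3 call ended in 11 of 21 other settings. Translation initiation genes Eif1a (0.61) and Eif3d (0.37) rose out of 29 (adjusted p = 0.11).

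No member was called at 8 h in wild type cells among 29 proteasome genes (camera adjusted p = 0.131) and 25 ribosomal protein genes (adjusted p = 0.828). Of 22 genes near Ddit3, Ddit3 and Tsfm (0.48) rose and Ctdsp2 (−0.82) and Mars1 fell, with a median of −0.04, a mean of 0.12 and an adjusted p of 0.987. The markers of other cell types had adjusted p of 0.746 for skeletal and cardiac muscle (0 of 11 called), 0.0857 for smooth muscle (1 of 10, Cnn1 at −0.55), 0.295 for leukocytes (0 of 13), 0.799 for epithelium (0 of 2), 0.295 for endothelium (1 of 2, Flt1 at −0.71), 0.39 for neural cells (2 of 6, Ncam1 at −0.69 and Tubb3 at −0.41), 0.451 for cartilage and bone (0 of 4) and 0.489 for adipocytes (0 of 2).

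Without CHOP the largest rise after 4 h was that of Herpud1, 2.77 log2 (SE 0.107, adjusted p = 6.45e-15). Rabepk rose by a fitted 2.03 (at least 3.25-fold), Gadd45a by 1.97, Piga by 1.90 and the ubiquitin ligase gene Siah2 by 1.55. Atf4 (0.93), Trib3 (1.34), Ppp1r15a (1.09), Dnajb9 (0.92) and Xbp1 (0.63) also rose. The other Dnajb9 probe set, in a fit of every probe set without the filter, rose by 1.84 (adjusted p = 0.0465). The largest falls were Gas1 (−1.56), Pclaf (−1.28), Mki67 (−1.20), Adm (−1.20) and Synpo (−1.16), of which Pclaf and Mki67 mark dividing cells. The Adm call ended in 11 of 20 other settings, with adjusted p up to 0.146. Ddit3 (0.92, adjusted p = 0.258), Hspa5 (0.38, adjusted p = 0.0616), Hsp90b1 (0.25, adjusted p = 0.687), Atf3 (1.24, adjusted p = 0.362), Asns (0.10, adjusted p = 0.784) and Ero1a (0.11, adjusted p = 0.854) were not called. For Hspa5 and Ero1a, both called in wild type cells, the difference between the responses was not called either (−0.18 and −0.50, adjusted p = 0.996 for both).

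In CHOP-/- cells at 4 h limma called 84 genes, 55 higher and 29 lower, and 27 changed at least 2-fold. At an unadjusted p under 0.05 there were 656 genes, and the arrays of 337 did not overlap (exact p 0.0286 each by chance). The count was 49, 53 and 50 without untreated arrays A, B and C, 52 and 47 without 4 h arrays B and D, and 53 without both arrays C. It was 48 on values as deposited, 38 with centring on the median, 53 without the filter and 20 with only the compared groups. Another split of these arrays, given in the closing section, called more genes than the real one.

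Of the 22 measured PERK-ATF4 genes 7 rose at 4 h in CHOP-/- cells, and 8 adjusted over the list alone, with Vegfa at 1.29 log2 (median 0.30, adjusted p = 5.18e-10). In ER-associated degradation 3 of 16 rose, and 4 adjusted over the list alone, with Sel1l at 0.57 (adjusted p = 0.000171). Chemokine and cytokine genes, NF-κB targets, rose in 6 of 20 cases, and 6 adjusted over the list alone, with Tnfaip3 (1.53), Cxcl1 (1.46), Ccl2 (0.68) and Csf1 (0.55) (median 0.54, adjusted p = 1.21e-06). These 3 lists were also called with an estimated correlation. ER chaperone genes rose in 5 of 22 cases, and 7 adjusted over the list alone, with Creld2 (1.40), Pdia4 (0.78) and Manf (0.72), at an adjusted p of 1.45e-06 and an adjusted p = 0.0925 with an estimated correlation. Cell cycle genes went down, with 2 of 42 fallen, Mki67 and Kif23 (−0.92), and 12 adjusted over the list alone (median −0.45, or −0.26 without untreated array C, adjusted p = 1.64e-14, and adjusted p = 0.0925 with an estimated correlation). The reported CHOP-dependent genes, not independent evidence, rose in 2 of 7 cases, and 2 adjusted over the list alone (median 0.11, adjusted p = 0.0166, and adjusted p = 0.0676 with an estimated correlation). Its median was 0.26 without 4 h array C. That call ended without 4 h array A (adjusted p = 0.0569), that of the tRNA synthetases (median 0.20, adjusted p = 0.0124, and adjusted p = 0.165 with an estimated correlation) without untreated array A (adjusted p = 0.0991), and that of matrix genes (median −0.10, adjusted p = 0.00217, and adjusted p = 0.38 with an estimated correlation) without 4 h array C (adjusted p = 0.128). The synthetase median was 0.12 without 4 h array C, and the matrix median went as far as −0.18 without 4 h array A or B. Among the named genes the calls of Csf1 and Pdia4 ended in 12 of 21 other settings each, that of Cxcl1 in 13 of 21 and that of Kif23 in 15 of 20.

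After 8 h in CHOP-/- cells Rabepk rose by a fitted 4.00 log2 (at least 12-fold), Ero1b by 3.91, Creld2 by 3.39, Piga by 3.01 and Herpud1 by 2.99 (SE 0.107, adjusted p = 1.17e-15). Dnajb9 rose by 1.93 log2, Trib3 by 1.72, Ppp1r15a by 1.45, Atf4 by 1.05, Hsp90b1 by 1.05, Hspa5 by 0.74, Ero1a by 0.60 and Xbp1 by 0.55. In a fit of every probe set without the filter, the other Dnajb9 probe set rose by 3.73 (adjusted p = 3.12e-06). In that fit the other Ero1a probe set was not called (0.44, adjusted p = 0.374). Nr4a1 (−3.76), Fos (−3.67), Id1 (−2.45), Idi1 (−2.32) and Ptger4 (−2.10) fell most. Ddit3 (0.44, adjusted p = 0.457), Atf3 (0.52, adjusted p = 0.59) and Asns (0.13, adjusted p = 0.408) were not called. Car6 lay under the filter's signal in all 12 CHOP-/- arrays.

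In CHOP-/- cells at 8 h 792 genes were called, 414 higher and 378 lower, with 201 changed at least 2-fold, 1529 at an unadjusted p under 0.05, and arrays of 1054 genes not overlapping (exact p 0.0286 each by chance). Called genes were higher in 52.3% of cases, or in 65.7% with centring on the median. Both genotypes shared 306 risen genes, where 39.9 would be shared if the calls were independent, and 205 fallen genes, where 26.2 would be. Only 1 gene, Vcam1, was called in opposite directions. Across all tested genes, which are not independent replicates, the 8 h changes of the genotypes had a correlation of 0.785, and those at 4 h a correlation of 0.473. At 4 h 40 risen and 6 fallen genes were shared and none was called in opposite directions by limma, out of 633 and 656 genes at an unadjusted p under 0.05.

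**Figure D3:**
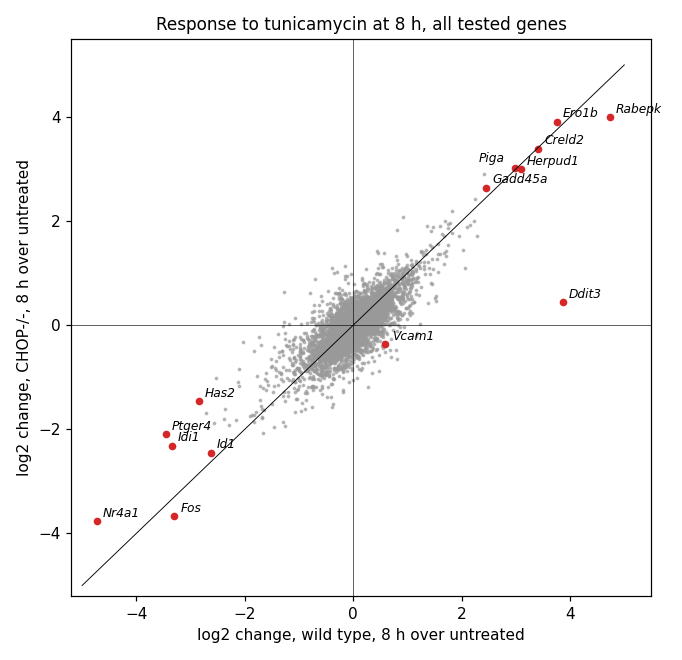
Log2 change from untreated to 8 h of tunicamycin in wild type cells (horizontal axis) and CHOP-/- cells (vertical axis) for all 5692 tested genes, with the line of equal change and named genes in red. Ero1b, Creld2, Herpud1, Piga and Id1 lie near the line, and Ddit3, Vcam1 and Rabepk lie below it. Has2, Ptger4, Idi1 and Nr4a1 fell less in CHOP-/- cells and lie above it. Only Ddit3 and Vcam1 had a called response difference.

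Without CHOP, ER chaperone genes rose at 8 h in 14 of 22 cases, and 17 adjusted over the list alone (median 0.62, adjusted p = 3.84e-14), and ER-associated degradation genes in 10 of 16, and 10 adjusted over the list alone (median 0.63, adjusted p = 1.44e-10). PERK-ATF4 genes rose in 10 of 22 cases, and 11 adjusted over the list alone, with Stc2 at 1.90 and Cebpg at 0.83 (adjusted p = 4.09e-09). The tRNA synthetase genes rose in 7 of 20 cases, and 13 adjusted over the list alone, with Wars at 1.08 (adjusted p = 2.28e-06). These 4 lists were also called with an estimated correlation. Transport genes rose in 15 of 43 cases, and 17 adjusted over the list alone, with 1 fallen, at an adjusted p of 5.34e-07 and an adjusted p = 0.155 with an estimated correlation. N-glycosylation genes rose in 5 of 21 cases, and 5 adjusted over the list alone, with Gmppb at 0.84 (adjusted p = 0.0194, and adjusted p = 0.052 with an estimated correlation). The reported CHOP-dependent genes, not independent evidence, rose in 3 of 7 cases, and 3 adjusted over the list alone (median 0.46, adjusted p = 0.0352, and adjusted p = 0.106 with an estimated correlation), a call that ended without untreated array A, untreated array B or 8 h array B (adjusted p up to 0.0662).

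Of 42 cell cycle genes 22 fell at 8 h in CHOP-/- cells, and 29 adjusted over the list alone, with Bub1 (−1.37), Mcm3 (−1.04), Aurka (−0.87) and Pcna (−0.83) (median −0.72, adjusted p = 5.59e-13, and adjusted p = 0.113 with an estimated correlation). In the cholesterol list 8 of 17 fell, and 11 adjusted over the list alone, with Sqle (−1.45), Hmgcs1 (−1.44) and Msmo1 (−1.25), while Mvd rose by 0.89 (median −0.73, adjusted p = 6.33e-06, and adjusted p = 0.233 with an estimated correlation). Immediate-early genes fell in 11 of 22 cases, and 11 adjusted over the list alone, with Ier3 (−1.31) and Dusp1 (−1.05) (median −0.56, adjusted p = 1.05e-05, and adjusted p = 0.248 with an estimated correlation). Matrix genes fell in 10 of 45 cases, and 11 adjusted over the list alone, with Mfap2 (−1.36), Col3a1 (−0.79) and Col8a1 (−0.76), at an adjusted p of 0.00132 and an adjusted p = 0.248 with an estimated correlation. Respiratory chain genes fell in 3 of 61 cases, and 3 adjusted over the list alone (adjusted p = 0.0181, and adjusted p = 0.716 with an estimated correlation), a call that ended without untreated array D or 8 h array B (adjusted p up to 0.277). Chemokine genes had a median of −0.06 and a mean of 0.05 (adjusted p = 0.702), with Relb (0.97), Ccl7 (0.88) and Nfkb2 (0.80) risen and Vcam1 fallen (−0.37, adjusted p = 0.0497), a call that ended in 14 of 21 other settings.

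Between 4 h and 8 h the ER chaperone list went on rising in both genotypes. In wild type cells Ero1b (1.98), Rabepk (1.68), Creld2 and Nme6 (1.28) rose most, and Nr4a1 (−3.21), Has2 (−2.46), Il6 (−2.43) and Idi1 (−2.38) fell most. Without CHOP Ero1b (2.77), Creld2 (2.00), Rabepk (1.97) and Akap17b (1.61) rose most, and Nr4a1 (−3.38), Cxcl1 (−2.48), Il6 (−2.17) and Idi1 (−2.05) fell most. ER chaperone genes rose in 8 of 22 cases in wild type cells, and 15 adjusted over the list alone (adjusted p = 1.97e-11), and in 11 cases in CHOP-/- cells, and 13 adjusted over the list alone (adjusted p = 1.45e-11). Both were also called with an estimated correlation, as was ER-associated degradation, with 4 of 16 and 6 of 16 risen. Cholesterol genes had medians of −0.56 in wild type cells, with 3 of 17 fallen, and −0.82 in CHOP-/- cells, with 7 of 17 fallen (adjusted p = 8.95e-07 and 2.41e-09, and adjusted p = 0.152 and 0.113 with an estimated correlation). Immediate-early genes fell in 4 and 3 of 22 cases (adjusted p = 4.34e-08 and 1.34e-07, and adjusted p = 0.135 and 0.16 with an estimated correlation), and chemokine genes in 5 and 4 of 20 cases (adjusted p = 0.000471 and 0.00341, and adjusted p = 0.123 and 0.16 with an estimated correlation).

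From 4 h to 8 h, 235 genes were called in wild type cells, 119 higher and 116 lower, and 315 in CHOP-/- cells, 194 higher and 121 lower. At an unadjusted p under 0.05 there were 859 and 1123 genes, and the arrays of 524 and 670 genes did not overlap (exact p 0.0286 each by chance). Called genes were higher in 50.6% of cases in wild type cells, or in 65.7% with centring on the median, and in 61.6% in CHOP-/- cells, or in 79.7% with centring. The wild type count was 139 without 4 h array C, 142 and 108 without 8 h arrays A and D, 108 with only the compared groups and 20 without arrays A and B. The CHOP-/- count was 120 and 134 without 4 h arrays C and D, 193, 183 and 154 without 8 h arrays A, C and D, 160 with only the compared groups and 133 without arrays C.

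Untreated CHOP-/- cells differed from untreated wild type cells in few genes besides Ddit3. The matrix genes Eln (2.20) and Col15a1 (2.13, SE 0.274, adjusted p = 9.91e-05), Strap (1.94), Amacr (1.66), Kcnk1 (1.57), the kinesin gene Kif20a (1.57 on its named probe set), Hoxa5 (1.51) and Rab3d (1.43) were higher in CHOP-/- cells. Cap1 (−1.99), AI506816 (−1.93), Adm (−1.62), Aebp2 (−1.47), Clta (−1.27), Mrvi1 (−1.24) and the mitochondrial protease gene Lonp1 (−1.08) were lower. For Kif20a the other tested probe set went the opposite way, with a mean genotype difference over the 3 times of −0.40 log2. Asns was higher by 0.50 log2 (adjusted p = 0.00463), and Mars1, beside Ddit3, was lower by 0.86 log2. Hspa5, Hsp90b1, Dnajb9, Herpud1, Xbp1, Atf3, Atf4, Trib3 (−0.34, adjusted p = 0.762), Ppp1r15a (−0.39, adjusted p = 0.598) and Ero1a (−0.23, adjusted p = 0.705) were not called.

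In untreated cells 56 genes were called between the genotypes, 35 higher and 21 lower in CHOP-/- cells, and 25 by at least 2-fold. There were 508 genes at an unadjusted p under 0.05, and the arrays of 300 genes did not overlap (exact p 0.0286 each by chance). The count was 35 without wild type array A, 35 without CHOP-/- array A, 88 with array weights, 23 with only the compared groups and 37 without wild type arrays A and B. Amino acid transporter genes were higher as a list, with Slc7a3 (1.33) and Slc7a7 (0.74) called out of 11 and 5 adjusted over the list alone (median 0.46, adjusted p = 8.77e-05), also with an estimated correlation. The reported CHOP-dependent genes were not called as a list in untreated cells (median −0.23, adjusted p = 0.172), with Atf5 (−0.88) lower, a call that ended in 13 of 21 other settings.

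Comparing the genotypes at 4 h, Ppp1r15a was lower in CHOP-/- cells by 1.04 log2 (adjusted p = 0.00353), with a signal of 485.1 ± 88.1 against 987.2 ± 132 (SD, n = 4). Ero1a was lower by 0.73 log2 (adjusted p = 0.00656), with 616.2 ± 149 against 1013 ± 166 (SD, n = 4), and Atf5, already lower untreated, was lower by 1.04 log2. The other Ero1a probe set, in a fit of every probe set without the filter, was not called (−0.49, adjusted p = 0.445). The response differences of Ppp1r15a and Ero1a at 4 h were not called (adjusted p = 0.996 for both). Trib3 was not called (−0.94, adjusted p = 0.0623). The chemokine gene Cxcl5 (−2.07), the pentraxin gene Ptx3 (−2.04), Aebp2 (−1.89), AI506816 (−1.78), Cap1 (−1.66), Mtm1 (−1.49) and Glce (−1.43) were the largest differences below wild type after Ddit3. Amacr (2.21), Rab3d (1.94), Col15a1 (1.66), Slc7a3 (1.55), Rgcc (1.46), Strap (1.37), Gucy1b1 (1.35) and Mfap4 (1.35) were the largest fitted differences above it. All wild type 4 h arrays of Amacr lay under the filter's signal, so it was at least 2.83-fold higher and its place is not certain. The calls of Cap1 and Strap ended in 12 and 14 of 21 other settings.

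As lists at 4 h, 3 of 7 reported CHOP-dependent genes were lower in CHOP-/- cells, and 4 adjusted over the list alone (median −0.73, adjusted p = 0.001), also with an estimated correlation. The list is not independent evidence. The PERK-ATF4 list was split, with Ppp1r15a and Atf5 among 4 lower genes and Vegfa (0.86), Pck2 (0.69) and Asns (0.35, a call that ended in 14 of 21 other settings) higher, or 5 lower and 4 higher adjusted over the list alone (median 0.04, mean −0.02, adjusted p = 0.99). Cell cycle genes were lower, with Mki67 (−1.38), Bub1 and Aurka (−0.72) among 5 of 42, and 19 adjusted over the list alone, while the named probe set of Kif20a was higher by 1.09 (median −0.45, adjusted p = 7.45e-12, and adjusted p = 0.312 with an estimated correlation). ER chaperone genes were not called as a list at any time (adjusted p = 0.857 untreated, 0.183 at 4 h and 0.872 at 8 h). Cholesterol genes were higher with Msmo1 at 1.01 and 2 of 17 adjusted over the list alone (adjusted p = 0.001, and adjusted p = 0.559 with an estimated correlation), a call that ended without CHOP-/- array C (adjusted p = 0.0611). Amino acid transporter genes Slc7a3, Slc7a7 (1.23) and Slc38a4 (1.12) were higher (adjusted p = 0.0423, and adjusted p = 0.169 with an estimated correlation), and that list call ended without any 1 of 5 arrays (adjusted p up to 0.178).

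At 4 h 142 genes were called between the genotypes, 67 higher and 75 lower, 52 of them by at least 2-fold, with 881 at an unadjusted p under 0.05 and arrays of 448 genes not overlapping (exact p 0.0286 each by chance). The count was 79 without wild type array B, 81 and 91 without CHOP-/- arrays C and D, 55 with only the compared groups and 37 without wild type arrays A and B.

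At 8 h Ero1a and Ppp1r15a were again lower without CHOP. Ero1a was lower in CHOP-/- cells by 0.79 log2 (adjusted p = 0.00196), at 872.4 ± 82.8 against 1501 ± 182 (SD, n = 4). The other Ero1a probe set, in a fit of every probe set without the filter, was called here (−0.98, adjusted p = 0.0352). Ppp1r15a was lower by 0.96 log2 (adjusted p = 0.0046), at 624.9 ± 69.7 against 1236 ± 112 (SD, n = 4), and Trib3 missed the threshold (−0.91, adjusted p = 0.0542). Car6, tested without the filter, was at least 4.14-fold lower in CHOP-/- cells at 8 h (adjusted p = 2.74e-08), where all their arrays lay under the filter's signal. Vcam1, an adhesion molecule gene, was lower by 0.92 log2 (adjusted p = 7.84e-05). Cd53 (−2.33), Chchd10 (−2.18), Entpd5 (−1.93), Ptx3 (−1.87), AI506816 (−1.85), Lonp1 (−1.84) and Aebp2 (−1.69) were the largest differences below wild type after Ddit3. Rab3d (2.03), Eln (1.90), the endothelin gene Edn1 (1.89), Col15a1 (1.88), Has2 (1.76), Npy1r (1.70), Amacr (1.64) and Adi1 (1.64) were the largest fitted differences above it. All wild type 8 h arrays of Rab3d and Npy1r lay under the filter's signal. These 2 genes were at least 1.97-fold and 2.36-fold higher, so their places are not certain. Cd53 is a leukocyte marker, and its call ended in 10 of 20 other settings, that of Edn1 in 14 of 21.

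Of the reported CHOP-dependent genes 3 of 7 were lower at 8 h, and 4 adjusted over the list alone, with Atf5 at −1.14 (median −0.79, adjusted p = 0.000359), also with an estimated correlation. In the PERK-ATF4 list Cdsn (−1.07) was among 4 lower genes and Vegfa (1.03) and Pck2 (0.48) were higher, or 6 lower and 4 higher adjusted over the list alone (median 0.13, mean −0.06, adjusted p = 0.872). Cell cycle genes were lower, with Bub1 (−0.97), Aurka (−0.69) and Mad2l1 (−0.67) called and 7 of 42 adjusted over the list alone, while the named probe set of Kif20a was higher by 1.23 (median −0.43, adjusted p = 4.52e-08, and adjusted p = 0.279 with an estimated correlation). NRF2 genes were lower with Sqstm1 at −0.77, and 2 of 25 adjusted over the list alone (adjusted p = 0.000663, and adjusted p = 0.0749 with an estimated correlation). Matrix genes were higher in 6 of 45 cases, and 9 adjusted over the list alone with 1 lower, among them Mmp14 (0.57) and Ccn2 (0.32) (adjusted p = 0.0142, and adjusted p = 0.403 with an estimated correlation), a call that ended without wild type array C (adjusted p = 0.119). Amino acid transporter genes stayed higher with Slc7a7 at 1.28 and Slc7a3 at 1.27 (adjusted p = 0.0187, and adjusted p = 0.0749 with an estimated correlation), a call that ended without CHOP-/- array B (adjusted p = 0.0504).

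At 8 h 237 genes were called between the genotypes, 128 higher and 109 lower, 92 of them by at least 2-fold, with 955 at an unadjusted p under 0.05 and arrays of 655 genes not overlapping (exact p 0.0286 each by chance). The count was 154 without wild type array A, 147 and 151 without CHOP-/- arrays A and B, 155 with centring on the median, 542 with array weights and 115 without wild type arrays A and B.

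Smaller lists were also called between the genotypes, none of them with an estimated correlation. Respiratory chain genes (untreated median −0.14, or −0.08 and −0.22 without CHOP-/- array C or D, adjusted p = 0.000205, and adjusted p = 0.651 with an estimated correlation) and ribosomal protein genes (untreated median −0.06, adjusted p = 0.00885, and adjusted p = 0.496 with an estimated correlation) were lower in CHOP-/- cells, and at 8 h both calls (adjusted p = 0.0397 and 0.0316) ended without wild type array C or D or CHOP-/- array B (adjusted p up to 0.31 and 0.0947). Endothelial markers were higher untreated (median 0.55, adjusted p = 0.0221, and adjusted p = 0.157 with an estimated correlation) and at 8 h (median 0.81, adjusted p = 0.00937, and adjusted p = 0.0749 with an estimated correlation). The untreated endothelial call ended without wild type array C (adjusted p = 0.108). Chemokine genes were lower untreated (median −0.25, adjusted p = 0.0221, and adjusted p = 0.496 with an estimated correlation), a call that ended without wild type array B or CHOP-/- array C (adjusted p up to 0.141). At 8 h smooth muscle markers (median 0.16, adjusted p = 0.0316, and adjusted p = 0.279 with an estimated correlation) were higher and adipocyte markers lower (median −0.77, adjusted p = 0.0254, and adjusted p = 0.0847 with an estimated correlation). Those calls ended without wild type array B or D (adjusted p up to 0.0776) and without wild type array A or CHOP-/- array D (adjusted p up to 0.0538).

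Across all 3 times 23 genes were higher and 15 lower in CHOP-/- cells, where 0.0093 and 0.0053 would be called each time if the calls were independent. They are not, since wild type arrays of the same letter correlated between times (0.25 to 0.62), which the expected counts leave out. The higher genes included Col15a1, Amacr, Rab3d, Adi1 and the transporter genes Slc7a3 and Slc7a7. The lower genes included Ddit3, the coat protein genes Arcn1 and Clta, Lonp1, Atf5 and Adm. The other tested Arcn1 probe set had a mean genotype difference over the 3 times of only −0.162 log2, against −0.862 on the named one. The Adm call at 4 h ended in 11 of 20 other settings (adjusted p up to 0.245) and the untreated Atf5 call in 13 of 21. Lonp1 stood at −1.08, −1.31 and −1.84 log2 untreated, at 4 h and at 8 h, and Amacr at 1.66, 2.21 and 1.64 log2.

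Leukocyte markers separated the arrays in a different way. Their list mean relative to all 24 arrays was 1.04 to 1.92 log2 in the 6 wild type arrays A and B, −0.85 to −0.29 in the 6 wild type arrays C and D and −1.46 to 0.22 in the 12 CHOP-/- arrays. The signal of the lysozyme gene Lyz2 was 633.5 to 1563.4 in wild type arrays A and B, 76.7 to 167.7 in C and D and 32.7 to 278.3 in CHOP-/- arrays. The list was lower in CHOP-/- cells by a median of −0.83 untreated, −0.86 at 4 h and −0.91 at 8 h (adjusted p = 0.00027, 0.00498 and 0.00407, and adjusted p = 0.651, 0.718 and 0.587 with an estimated correlation), and reversed to 0.16, 0.12 and 0.12 without wild type arrays A and B. The untreated median was −0.47 without wild type array A, and the medians at 4 h and 8 h were −0.49 and −0.50 without wild type array B. These calls also ended without wild type array B in untreated cells (adjusted p = 0.0549) and at 8 h (adjusted p = 0.12), and at 4 h without wild type array A or B or CHOP-/- array B or D (adjusted p up to 0.151).

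**Figure D4:**
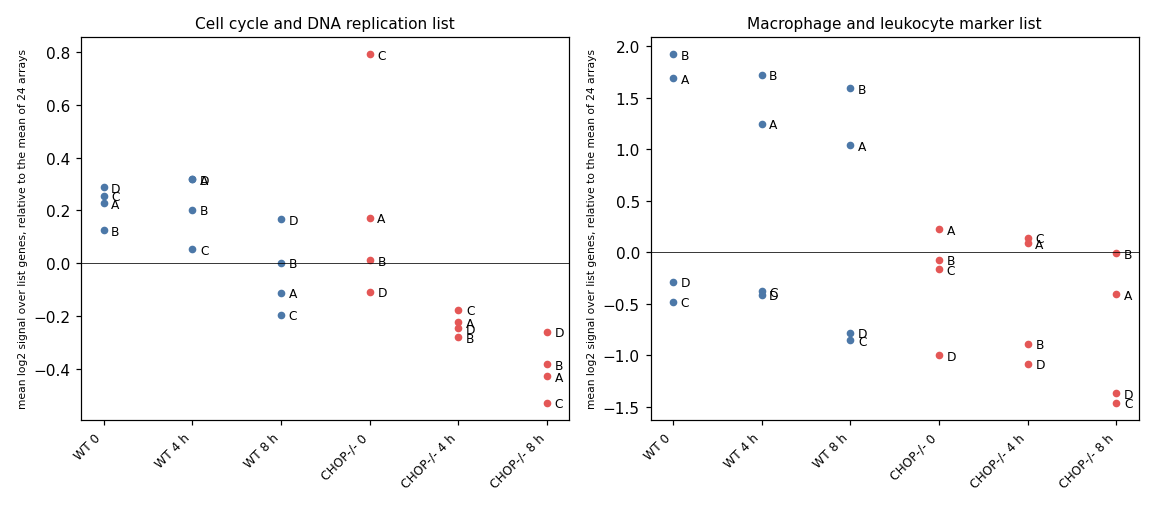
Mean log2 signal of the cell cycle list (left) and of the leukocyte marker list (right) in each array, relative to the mean of 24 arrays (vertical axes), for the 6 groups, with letters naming the arrays. Untreated CHOP-/- array C stands highest for cell cycle genes at 0.79, and wild type arrays A and B stand highest for leukocyte markers.

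The response difference asks directly whether CHOP shaped the change after tunicamycin. At 8 h Ddit3 itself (fitted −3.43, SE 0.495, adjusted p = 0.00255) and Vcam1 (−0.96, SE 0.175, adjusted p = 0.0384) were called. Vcam1 rose in wild type cells from a signal of 619.5 ± 60.5 to 948.3 ± 121 and fell in CHOP-/- cells from 651.3 ± 54.3 to 497.1 ± 52 (SD, n = 4). Ero1a (−0.56, adjusted p = 0.989), Ppp1r15a (−0.58, adjusted p = 1) and Trib3 (−0.56, adjusted p = 1) leaned the same way without a call, and Hspa5 was at 0.00. Car6 was called without the filter (adjusted p = 0.000593), but no size can be given, since its untreated and CHOP-/- arrays all lay under the filter's signal. The Vcam1 call ended in 17 of 29 other settings, with adjusted p from 0.00257 to 0.999, and the Ddit3 call ended in 1, without wild type arrays A and B (adjusted p = 0.72). At 4 h limma called 0 genes, with 230 at an unadjusted p under 0.05, and Ddit3 stood at a fitted −2.68 (adjusted p = 0.0938). Neither Ddit3 value is an exact size, since 3 of 4 untreated CHOP-/- arrays, 1 of 4 at 4 h and 3 of 4 at 8 h lay under the filter's signal. At 8 h 262 genes had an unadjusted p under 0.05, which is 4.6% of those tested.

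Of the gene lists, 4 carried called response differences at both times. The reported CHOP-dependent genes, not independent evidence, had a median difference of −0.48 at 4 h and −0.49 at 8 h, with 0 of 7 called by limma and 7 of 7 below 0 at 8 h (adjusted p = 0.0247 and 0.0136, and adjusted p = 0.257 and 0.0929 with an estimated correlation). The 4 h call ended without any 1 of 5 arrays (adjusted p up to 0.166) and the 8 h call without untreated CHOP-/- array D (adjusted p = 0.059). The 4 h median was −0.30 without CHOP-/- 4 h array C (adjusted p = 0.0494), and the 8 h median −0.30 without untreated wild type array B (adjusted p = 0.0211). Cell cycle genes went further down in CHOP-/- cells, by a median of −0.44 at 4 h and −0.34 at 8 h (adjusted p = 1.81e-12 and 1.08e-08, and adjusted p = 0.413 and 0.331 with an estimated correlation). Without untreated CHOP-/- array C the cell cycle median was −0.22 at 4 h (adjusted p = 1.79e-05) and −0.13 at 8 h (adjusted p = 0.0125). Cholesterol genes went down less in CHOP-/- cells, by 0.51 at 4 h and 0.25 at 8 h (adjusted p = 3.66e-06 and 0.0427, and adjusted p = 0.456 and 0.606 with an estimated correlation), and the 8 h call ended without any 1 of 7 arrays (adjusted p up to 0.535), with a median of 0.03 without untreated CHOP-/- array C. The 4 h median of cholesterol biosynthesis and uptake was 0.26 without CHOP-/- 4 h array C, 0.32 without untreated CHOP-/- array C (adjusted p up to 0.00204) and 0.18, with no call, without both (adjusted p = 0.203). Immediate-early genes differed by 0.24 and 0.25 (adjusted p = 0.00636 and 0.0427, and adjusted p = 0.631 and 0.606 with an estimated correlation), and these calls ended without any 1 of 5 and of 8 arrays (adjusted p up to 0.451 and 0.753), with medians down to 0.07 and 0.04 without untreated CHOP-/- array C and up to 0.43 at 4 h without untreated CHOP-/- array D. ER chaperone genes did not differ as a list at 4 h (median −0.09, adjusted p = 0.286) or at 8 h, where the median was 0.02, the mean 0.01 and the test direction down (adjusted p = 0.995).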

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

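Tests on the chromosome of Ddit3, on other probe sets, on untreated CHOP-/- array C and on the untreated level of cell cycle genes were chosen only after the result was seen, as were the settings without CHOP-/- arrays C and without wild type arrays A and B.

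Besides Ddit3, 37 genes differed between the genotypes at all 3 times. A chromosome segment carried along with the deletion is argued against, since 0 of the 37 lay on the chromosome of Ddit3, which holds 4.7% of the tested genes, and they were spread over 16 chromosomes. Without the 6 wild type arrays A and B, which held the leukocyte markers, all 37 kept their sign. The median ratio of the differences was 1.02 (0.7 to 1.42), so these 37 differences did not rest on those arrays. A gene that differs only in arrays A and B spreads widely within its groups and tends to miss the calls. The choice of the 37 therefore favoured this outcome, and it says nothing about other genes. Sequence differences under single probe sets may play a part. On the other probe sets the median ratio was −0.02, within the bound set for this explanation, and 3 of 6 had the same sign. The sign was opposite for Kif20a (−0.399 against 1.295), Agap1 (0.227 against −1.026) and Inpp1 (0.363 against −0.81). However, only 6 of the 37 genes had another tested probe set. The limit on that share, which leaves the explanation open, was added after the value was seen. Loss of CHOP and any difference of strain or embryo between the genotypes coincide in the design, so that loss of CHOP stays open as untested.

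Cell cycle genes went further down after tunicamycin in CHOP-/- cells, with a median response difference of −0.44 at 4 h and −0.338 at 8 h, where 39 of 42 members were below 0, but the list was not called with an estimated correlation (adjusted p = 0.413 and 0.331). Quantile normalization is argued against as the cause, since the 8 h value was −0.385 on the values as deposited. For a higher level in untreated CHOP-/- cells, the median genotype difference was −0.04 untreated but −0.425 at 8 h (quartiles −0.586 to −0.207). That met the bound set against this explanation, but it decides nothing, since untreated CHOP-/- array C raised the untreated value. The larger share of the 8 h response difference went with untreated CHOP-/- array C, whose list mean was 0.791 against −0.108 to 0.173 in the other untreated CHOP-/- arrays: without it the median moved from −0.338 to −0.131, past the bound set for that array as the cause, and was still called (adjusted p = 0.0125). At 4 h the median was −0.22 without that array. The untreated genotype difference was then −0.241, so that a lower level of these genes in CHOP-/- cells before treatment stays open, as does an effect of CHOP on cycling, which was not tested.

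Rabepk rose by a fitted 4.73 log2, at least 15.8-fold, at 8 h in wild type cells while Hspa5, its neighbour in GRCm38.p6, rose by 0.74 log2. Its probe set could in part read RNA of Hspa5, and within groups Hspa5 stood at percentile 96 of 5691 genes by correlation with Rabepk (r = 0.56 across arrays), which neither reached the top 1% set for that explanation nor fell below the median. Compression of abundant signals may also shrink the rise of Hspa5, and over 22 ER chaperone genes the untreated level and the rise had a Spearman correlation of −0.28 (permutation p = 0.21), which leaves it open. A shared ER stress element between the genes was not tested here.

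Every way of splitting the 8 arrays of a comparison into equal groups was counted, 35 in all. Only 1 of 35 splits, the real one, reached the real count for CHOP-/- cells at 8 h (792 genes, highest other split 9). The same held for CHOP-/- cells from 4 h to 8 h (315 and 1). It also held for CHOP-/- against wild type cells untreated (56 and 14) and at 4 h (142 and 63). Each share was under 0.05, which argues against chance in the split of these arrays. The count takes the arrays as independent and was not adjusted over the comparisons, so chance and a structure of the samples are not excluded. Where residuals pair the arrays by letter, only 8 splits part every pair, too few for a share under 0.05. The real one of these called 121 genes in wild type cells at 4 h, 944 at 8 h and 235 from 4 h to 8 h, and 237 between the genotypes at 8 h, and the highest other called 0 in each. The splits that part fewer pairs called up to 84, 45, 58 and 2 genes. For CHOP-/- cells at 4 h chance cannot be excluded, since 2 of 35 splits reached the real 84 and another split called 455 genes. That split set untreated arrays A and C with 4 h arrays A and B against the rest, which points to a structure of the samples. For the response difference at 8 h, 7 of 100 drawn splits reached the 2 genes (highest other 161). These draws shuffle the genotypes separately at each time, so that constant genotype differences can turn into response differences. They therefore cannot decide, and chance is not excluded. At 4 h the splits decide nothing, because with 0 genes called each of the 100 reached the real count (highest other 112).

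Single arrays stood apart from the rest of their group in 3 of 150 groups, where 7.5 would by chance. Atf3 had a signal of 1274 in wild type 4 h array C against 402.9 to 508.3 in the others. Ero1a had a signal of 786.1 in untreated wild type array D against 603.8 to 631.1 in the others. The PERK-ATF4 list mean was 0.2 in CHOP-/- 8 h array B against 0.26 to 0.27 in the others.

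The responses of the genotypes differed by test for 2 genes at 8 h, Ddit3 (fitted −3.426, not an exact size, since 3 of 4 CHOP-/- arrays untreated and at 8 h lay under the filter's signal) and Vcam1 (−0.962), and for Car6 without the filter (fitted −3.228, not an exact size, since its untreated and CHOP-/- arrays all lay under the filter's signal). At 4 h they differed for the lists of reported CHOP-dependent genes (−0.477), cholesterol genes (0.509), immediate-early genes (0.236) and respiratory chain genes (0.157). The respiratory chain call (adjusted p = 0.00129) ended without wild type 4 h array A or CHOP-/- 4 h array C (adjusted p up to 0.258), with medians from 0.061 to 0.238 over 16 arrays. Without any 1 of 5 arrays the 4 h calls of the CHOP-dependent genes (adjusted p up to 0.166) and of the immediate-early genes (up to 0.451) ended. At 8 h they differed for the reported CHOP-dependent genes (−0.491), cholesterol genes (0.249), NRF2 genes (−0.134), immediate-early genes (0.25), chemokine genes (0.316) and smooth muscle markers (0.224). The CHOP-dependent call ended without untreated CHOP-/- array D (adjusted p = 0.059), the cholesterol call without any 1 of 7 arrays (adjusted p up to 0.535) and the immediate-early call without any 1 of 8 (up to 0.753). The NRF2 call ended without any 1 of 13 arrays (median −0.193 to −0.088, adjusted p 0.0271 to 0.132 over 16 arrays), and the chemokine and smooth muscle calls without any 1 of 10 arrays (medians from 0.083 to 0.427 and from 0.151 to 0.279, adjusted p up to 0.243 and 0.119). With the cell cycle list included, none of these lists was called with an estimated correlation.

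Among probe sets without a single gene name, which no comparison above uses, 83 of 679 tested were called at 8 h in wild type cells, 45 higher and 38 lower, and 18 changed at least 2-fold.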

How the results depend on the processing

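The settings without the untreated and 4 h CHOP-/- arrays C and without the 6 wild type arrays A and B were chosen after seeing the data. Without wild type A and B, fewer arrays left 21 called genes at 4 h and 296 at 8 h in wild type cells, 20 from 4 h to 8 h, 37 between the genotypes untreated, 37 at 4 h and 115 at 8 h, and 0 in the 8 h response difference. There the leukocyte list reversed to 0.161 untreated, 0.123 at 4 h and 0.117 at 8 h (adjusted p = 0.55, 0.934 and 0.822), because the arrays with its high values were gone. Without CHOP-/- arrays C the counts were 53 at 4 h, 133 from 4 h to 8 h and 1 in the 8 h response difference.

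With each array centred on its median 80 genes were called at 4 h in wild type cells, 38 at 4 h in CHOP-/- cells, 155 between the genotypes at 8 h and 1 in the 8 h response difference. Array weights gave 190 and 1469 genes at 4 h and 8 h in wild type cells, 88 and 542 between the genotypes untreated and at 8 h, and 5 in the 8 h response difference. With only the groups compared, and so fewer arrays, the counts were 70 and 20 at 4 h in wild type and CHOP-/- cells, 108 and 160 from 4 h to 8 h, 23 and 55 between the genotypes untreated and at 4 h, and 1 in the 8 h response difference. At 4 h in CHOP-/- cells 48 genes were called on values as deposited and 53 without the filter. The 4 h response difference had 1 gene with the pseudocount at the 40th percentile and 1 with a block for the letters, and the 8 h one had 1 with every probe set and 1 without an intensity trend. Except for the loss of arrays, the cause was not tested.

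Leaving out each array in turn gave 62 to 114 genes at 4 h and 721 to 818 at 8 h in wild type cells, 47 to 66 and 577 to 739 in CHOP-/- cells, 108 to 188 and 120 to 408 from 4 h to 8 h, 35 to 52, 79 to 148 and 147 to 206 between the genotypes at the 3 times, and 0 to 1 and 1 to 2 in the response differences.

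Of 457 calls of named genes, 360 were kept with centring on the median, 363 with only the groups compared, 432 on values as deposited, 425 without the filter, 448 with array weights, 456 with the block, 269 without wild type A and B and 420 without CHOP-/- arrays C, and none reversed in any setting. Of 105 list calls, 26 were kept with an estimated correlation, 99 on values as deposited, 92 without the filter, 100 with the block and 86 without wild type A and B. The block moved no other count of called genes by over 1.5 times. It gives each letter the same shift in all groups, whereas residuals paired by letter only between some groups. It therefore does not model that pairing and cannot show what the pairing would change. Genes near background limit the tests, since the pseudocount shrinks their fold changes.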

Other observations

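The nonsense-mediated decay tests and their 3 lists were chosen only after the rise of the genes that prompted them was seen, and the genes of this part were chosen after their values were seen.

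Several single genes outside the lists fell at 8 h of tunicamycin, and no list of genes like them was tested. In wild type cells Id1 fell by 2.63 log2 (SE 0.187, adjusted p = 7.53e-10), Id2 by 1.80 (adjusted p = 7.3e-05) and Id4 by 1.01 (adjusted p = 0.00151), all 3 of them genes of inhibitors of DNA binding. The MAP kinase phosphatase gene Dusp6 fell by 1.13 log2, the receptor inhibitor gene Errfi1 by 2.72, the repressor gene Hes1 by 1.12 and the hyaluronan synthase gene Has2 by 2.85. In CHOP-/- cells Id1 (−2.45), Id2 (−1.67) and Has2 (−1.47) fell too. At 4 h in wild type cells Id1 (−0.80) and Dusp6 (−0.70) were already lower, while Id2 (−0.06, adjusted p = 0.997), Id4 (0.14, adjusted p = 0.919) and Has2 (−0.39, adjusted p = 0.691) were not called.

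Snhg5, Taf1d, Snhg1 and Clk4, 4 genes picked out by their rise, were called in both genotypes. At 8 h in wild type cells Snhg5, a host of small nucleolar RNAs, rose by 2.42 log2, Taf1d by 1.82, Snhg1 by 1.47 and the splicing kinase gene Clk4 by 1.10. Without CHOP Snhg5 rose by 2.91, Taf1d by 2.18, Snhg1 by 1.88 and Clk4 by 1.12. Piga rose from a signal of 101.1 ± 17.1 to 847.1 ± 96.8 in wild type and from 108.4 ± 5.19 to 909.4 ± 114 in CHOP-/- cells (SD, n = 4).

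Transcripts of this kind are targets of nonsense-mediated decay, and less of it while translation is held back may be behind the rise of Snhg1, Snhg5, Taf1d and Clk4. It was tested on 3 other classes of decay targets at 8 h in wild type cells. The 7 other measured hosts of small nucleolar RNAs had a median of 0.815, with Rabggtb (0.90) and Nop56 (0.82) risen and 5 risen adjusted over the list alone, with an adjusted p of 0.00362, or 0.147 with an estimated correlation. The 16 splicing factors with poison exons had a median of 0.312, with 5 risen and 1, Srsf5 (−0.62), fallen (adjusted p = 0.00558, or 0.232 with an estimated correlation). Of the decay factors, which the pathway itself limits, 1 was measured, Smg5 at 0.439 (adjusted p = 0.26), so that the explanation is left open. At 8 h in CHOP-/- cells 4 of the 7 hosts and 4 of the 16 splicing factors rose, and Smg5 stood at 0.59 without a call. At 4 h in CHOP-/- cells 0 of the 7 hosts and 0 of the 16 splicing factors rose (medians 0.082 and 0.076, camera adjusted p = 0.464 for both). In wild type cells at 4 h 1 host and 2 splicing factors rose (medians 0.396 and 0.222). Their camera adjusted p was 0.00195 and 0.000293, or 0.0917 for both with an estimated correlation.

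Arrays also differed outside the design. The untreated and 4 h CHOP-/- arrays C had the lowest array weights, 0.48 and 0.52.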
